A study of Mus musculus with 12 samples.

How the data were processed

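RNA sequencing of mouse spleen was analysed from 12 libraries, 3 biological replicates for each of PBS at 3 h and ExPEC at 3, 6 and 12 h after intraperitoneal injection, per the labels. Total RNA was isolated with mirVana reagents and libraries were made with a TruSeq RNA kit, per the labels' protocols. Whether the libraries kept the strand, and the sex of the mice, are not stated there. Per the submitters' processing notes, reads were aligned to mm10 with HISAT2 2.0.4, and Cufflinks 2.1.1 and Cuffdiff were used for expression values. The deposited table holds a read count and an FPKM value for each gene and library, with KEGG pathway terms. The program that made the counts is not stated. The deposited FPKM values followed from the deposited counts to within 0.083% with 1 length per gene and 1 total per library. They were used for that check alone.

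The design written before the data were examined allowed for FPKM or counts. The table held whole counts, so the test planned for counts was used. Of 34745 genes, 10876 had a count of 0 in all libraries. Of the gene identifiers, 34267 were found in GENCODE vM21, 80.8% of them with the same span, and overlaps with other genes were taken from the spans in the table. Total counts ran from 9951153 (PBS replicate 2) to 24412926 (12 h replicate 1). A floor of 3 counts, the upper 95% limit for a count of 0, equalled 0.12 to 0.30 CPM. Intervals and floors cover counting error alone, not differences between mice.

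Counts were analysed in R 4.3.3 with edgeR 4.0.16 and limma 3.58.1. filterByExpr by group left 16075 genes, library sizes were scaled by TMM, and all 12 libraries entered 1 quasi-likelihood fit with 4 group means (prior count 2). The biological coefficient of variation was 12.2% and the prior degrees of freedom 4.17. Tests were two-sided, with Benjamini-Hochberg adjustment within each comparison. A gene was called at an adjusted p under 0.05 and a change of at least 2-fold, and rose, fell, higher and lower refer to such calls unless another measure is given. The 5 comparisons were ExPEC at 3, 6 and 12 h against PBS, 6 h against 3 h and 12 h against 6 h of infection, and an F-test covered all 4 groups. The same steps were tested on simulated data with known changes before use. Of 100 genes with a true 2-fold change, 97% passed the adjusted p but only 41% were called. Of 100 genes with a true 4-fold change, 100% were called. The changed genes were drawn from those at a mean of 5 CPM or more, and only the 3 h infected group was changed. The simulated spread followed the trend with expression and left out further differences in spread between genes. A gene that was not called may thus still have changed by about 2-fold, and by more if it was under 5 CPM or had a wide spread, which was not simulated.

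The 36 gene lists were fixed before the data were examined and tested with camera (preset correlation 0.01), adjusted over all 180 tests of 36 lists in 5 comparisons. The tests were repeated with a correlation estimated per list, and list members were also adjusted over the list alone. Of 639 distinct list genes, 633 were matched by symbol and 3 by identifier, and 3 (Faim3, Igj and Ahsp) were not matched. KEGG terms with 10 to 500 tested genes were tested among called genes with a one-sided hypergeometric test against the 5194 tested genes that carry a term, adjusted within comparison and direction. The hypergeometric test takes genes as independent, so all KEGG p-values given here may be too small where genes vary together. They do not measure differences between replicates.

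Genes named in the text were chosen by a rule fixed before the data were examined. For each comparison with PBS these were the 10 largest rises and 10 largest falls among called genes whose 3 infected libraries all lay beyond all 3 PBS libraries and whose mean in the higher group was at least 5 CPM. Between infected times the 5 largest of each were taken. Not every gene that the rule picked is reported here. Clone names and immunoglobulin segments were passed over, and members of the gene lists were named with their values. CPM values are group means with SD, and log2 changes are those of the fit with its SE. Where a group had no counts, the change is given as a lower bound against the floor of 3 counts in each of its libraries. With 1 to 3 counts a ratio with its 95% counting interval is given. Shared sequence was measured as the percentage of 50-base words of the transcripts that occur in another gene, and 59 of 643 named and list genes had at least 20%.

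Alternatives were a prior count of 0.125, no filter, DESeq2 size factors, quantile normalization with limma, the DESeq2 1.42.0 Wald test (a likelihood ratio test for the 4 groups), only the 2 groups compared, no minimum fold, replicate number as a block, each library left out in turn, and for lists the estimated correlation and fry, which tests a list against no change, a different hypothesis from that of camera, which tests it against other genes. Chosen after seeing the data were leaving out 2 libraries together, leaving out overlapping genes, and repeating the list and KEGG counts with each library left out. Comparisons with the same PBS libraries were set against 20 simulations of groups with no change, and every comparison was repeated on other splits of its libraries. Exact permutation and Fisher exact tests used scipy 1.17.1, with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.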

Results

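Spleen RNA was sequenced from BALB/c mice injected intraperitoneally with extraintestinal pathogenic Escherichia coli (ExPEC, strains that cause disease outside the gut) or with phosphate-buffered saline (PBS). The spleen filters blood and holds macrophages that recycle red cells, lymphocytes in the white pulp and, in mice, blood-forming cells. The labels gave 4 groups of 3 biological replicates, namely PBS at 3 h and ExPEC at 3, 6 and 12 h after injection. Total counts per library were 20754716, 9951153 and 18527623 for PBS, 19709154, 14495487 and 13011645 for 3 h, 20431970, 24327552 and 23743911 for 6 h, and 24412926, 24120770 and 19479140 for 12 h. A count of 3 in 1 library corresponded to 0.12 to 0.30 CPM (counts scaled to library size). Of 34745 genes listed, 23869 had a count in at least 1 library and 16075 were tested. The biological coefficient of variation was 12.2%.

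The first 2 principal components of log2 CPM held 53.0% and 17.4% of the variance. On component 1, 3 h replicate 3 was at -0.4, nearer to PBS (-78.2, -82.1 and -80) than 3 h replicates 1 and 2 (18.2 and 17.4). Expression differed among the 4 groups for 10359 of the 16075 genes (edgeR quasi-likelihood F-test, adjusted p under 0.05). Against PBS, 3344 genes were called at 1 or more times, a call being an adjusted p under 0.05 with at least a 2-fold change. PBS was sampled at 3 h alone, so the 3 h comparison is matched in time, whereas at 6 and 12 h the time after injection and the infection change together.

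**Figure D1:**
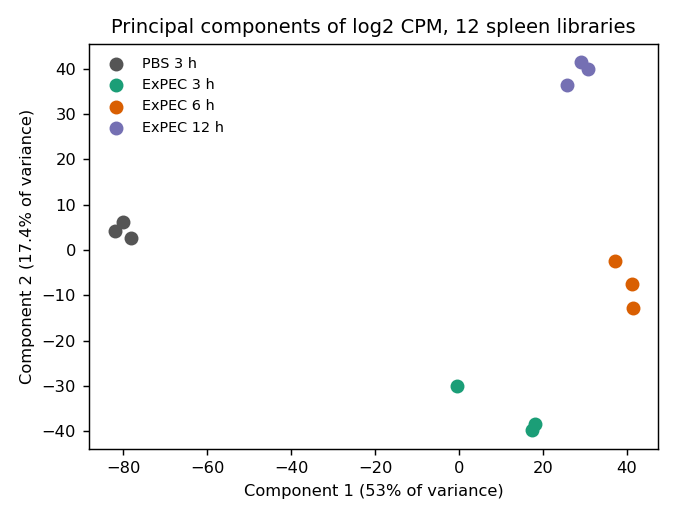
Principal components of log2 CPM of the 12 libraries (points), coloured by group, with component 1 (53.0% of the variance) on the horizontal axis and component 2 (17.4%) on the vertical axis.

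**Figure D2:**
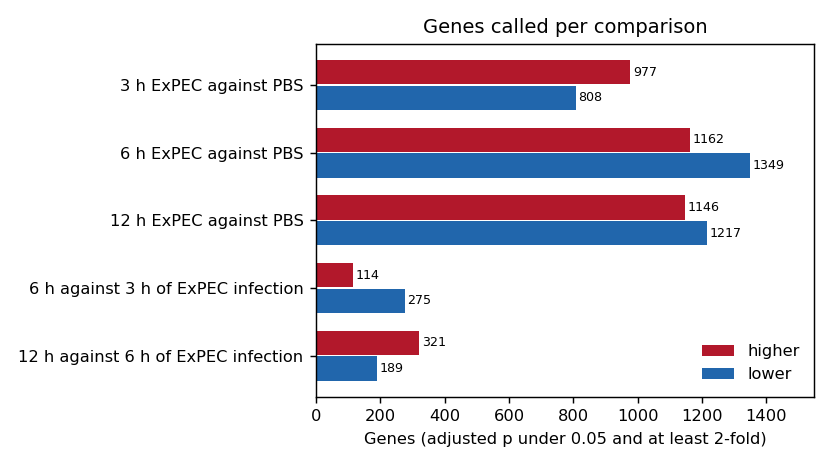
Genes called higher (red) or lower (blue) in each of the 5 comparisons, on an axis of gene counts that starts at 0. The bars run from 114 to 1162 genes higher and from 189 to 1349 genes lower.

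The 3 h comparison asked how the spleen transcriptome differed from that of time-matched control mice. Among the genes picked by the rule, Cxcl1 and Cxcl2, chemokines that draw in neutrophils, rose the most. Cxcl1 (ENSMUSG00000029380, chromosome 5, 90891241 to 90893115 in mm10), was at 324 ± 59.1 CPM against 0.732 ± 0.381 in PBS (SD, n = 3 each), a rise of 8.73 ± 0.24 (SE) on the log2 scale (adjusted p = 9.36e-11). Its neighbour Cxcl2 (chromosome 5, 90903871 to 90905938) rose by 8.12 ± 0.32. The other leading rises were Ptgs2, the inducible prostaglandin synthase (7.75), Fgf23, a phosphate-regulating hormone (7.64), the aggrecan-cleaving protease Adamts4 (7.56), the collagenase Mmp13 (7.34), Csf3, the granulocyte growth factor (7.32), the chemokine Ccl4 (6.99), Irg1, which makes itaconate (6.89), and Il6 (6.88). Without PBS replicate 1 the rise of Irg1 was 7.49. Adamts4 overlaps another gene, and without a stated strand its counts are uncertain.

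Among the inflammation lists at 3 h, 17 of 19 tested pro-inflammatory cytokines rose and none fell. Tnf was at 413 CPM (log2 change 5.22), Il1b from 28.8 to 553 CPM (4.26) and Il12b, a subunit shared by interleukins 12 and 23, from 1.35 to 30.0 CPM (4.42). Il22, which acts on epithelial cells, had no counts in PBS and 507 counts at 3 h, which made it at least 60.9-fold higher against a floor of 3 counts in each PBS library. Il17a had 0 and 61 counts, at least 7.55-fold higher. Il12a (0.38) and Csf1 (0.99) were not called, but Csf1 passed at 1.03 without PBS replicate 1, 1.01 without PBS replicate 3, 1.02 without 3 h replicate 2 and 1.04 without 3 h replicate 3. Of 25 chemokines, 21 rose, among them Cxcl10 (6.17), Ccl3 (6.41) and Ccl2 (6.79), while Ccl6 fell by 1.09 (by 0.97, under the fold limit, without 3 h replicate 2) and Cxcl12, made by stromal cells, was not called (-0.27). Il1b, Cxcl10 and Ccl6 overlap other genes, so their counts are uncertain. Ccl20 had 0 counts in PBS and 29 at 3 h, at least 3.51-fold higher. Brakes on inflammatory signalling rose in 21 of 23 cases, including Il1rn, the interleukin 1 receptor antagonist (5.45), Tnip3 (5.17), Socs3 (3.67), Tnfaip3 (3.31) and Cd274, the checkpoint ligand PD-L1 (3.14). Arg1, an arginase of alternatively activated macrophages, fell by 2.27. List medians were 4.26, 3.45 and 2.39 on the log2 scale, and the first 2 were the same with Il22, Il17a and Ccl20 set to their bounds. Camera adjusted p was 4.51e-39, 8.2e-56 and 2.49e-46, and 0.0178, 0.0108 and 0.0225 with an estimated correlation.

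Interferon-regulated genes rose together at 3 h. In the type I interferon list 23 of 24 genes rose, with Ifit1 at 4.93, Mx1 at 4.45 and Isg15, a ubiquitin-like protein, at 3.76, and Isg20 (0.77) was not called. In the interferon-gamma list 17 of 20 rose, including the guanylate-binding protein genes Gbp5 (4.48), Gbp2b (3.58) and Gbp2 (3.01) and Nos2, the inducible nitric oxide synthase (2.14). Ciita, the class II transactivator (-0.35), Irf8 (0.35) and Slamf8 (-0.41) were not called. List medians were 3.08 and 2.89, with camera adjusted p of 1.06e-77 and 7.28e-57, and 0.0178 and 0.0108 with an estimated correlation. Gbp6, Tgtp1, Tgtp2 and Ifit3 share 75.4%, 80.7%, 84.8% and 51.5% of their 50-base words with another gene, so the split of reads among such relatives is uncertain. Ciita overlaps Dexi.

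Receptors for bacterial products went in both directions at 3 h. Cd14, the lipopolysaccharide co-receptor, rose by 4.56 and Tlr2, a lipoprotein receptor, by 2.22, whereas Tlr4, the lipopolysaccharide receptor, was not called (-0.23) and the flagellin receptor Tlr5 fell by 1.54. In the Toll-like receptor and NF-kB list 7 of 29 genes rose and 2 fell (camera adjusted p = 6.35e-08, but adjusted p = 0.0986 with an estimated correlation). Inflammasome genes rose in 6 of 16 cases, led by Nlrp3 (3.13) and Casp4, the sensor of cytosolic lipopolysaccharide (2.27), and Nlrp1b fell by 1.48, or by 2.08 without 3 h replicate 3 (adjusted p = 2.78e-07, 0.041 with an estimated correlation). Acute phase and antimicrobial genes rose in 15 of 21 cases, among them Saa3 (5.01), Lcn2, which binds bacterial siderophores (3.02), and Serpina3n (2.73), with adjusted p = 5.16e-18, but adjusted p = 0.0544 with an estimated correlation. Saa2 had 1 count in PBS and 26 at 3 h, a ratio of 31.1 (95% counting interval 5.11 to 1280), and shares some of its words with another gene.

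The immediate early, metallothionein, glucocorticoid and heat shock lists each held called genes at 3 h. Immediate early genes rose in 11 of 14 cases, such as Atf3 (3.90), Nr4a3 (3.29) and Fos (2.24), with adjusted p = 1.29e-14, 0.041 with an estimated correlation. Metallothionein and oxidative stress genes rose in 6 of 15, with Mt2 at 4.22, Mt1 at 3.30 and the mitochondrial superoxide dismutase Sod2 at 2.55, while Hmox1, which degrades haem, fell by 1.01 (list adjusted p = 2.63e-11, 0.0361 with an estimated correlation). Its fall was under the fold limit without PBS replicate 1 (-0.97), 3 h replicate 1 (-0.98) or 3 h replicate 2 (-0.88). Glucocorticoid-induced genes rose in 4 of 14 (Mt2, Cdkn1a at 4.05, Errfi1 at 2.76 and Dusp1 at 2.16) and Cd163 fell by 2.53, or by 3.16 without 3 h replicate 3 (adjusted p = 9.23e-07, 0.041 with an estimated correlation). Of 14 heat shock genes, 3 rose, with adjusted p = 0.00241 but adjusted p = 0.168 with an estimated correlation. These were Hspb1 (1.04, but 0.82 without 3 h replicate 1), which shares 54.9% of its words with another gene, and the near-identical pair Hspa1a (1.81) and Hspa1b (1.52). Hspa1a missed the adjusted p without PBS replicate 2 (1.82), PBS replicate 3 (1.67), 3 h replicate 1 (1.82) or 3 h replicate 2 (1.78). Hspa1b missed it without PBS replicate 1 (1.43), PBS replicate 2 (1.60), PBS replicate 3 (1.54), 3 h replicate 1 (1.43) or 3 h replicate 3 (1.43).

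Coagulation genes rose in 8 of 20 cases and apoptosis genes in 5 of 22 at 3 h (adjusted p = 2.52e-06 and 0.000287, but adjusted p = 0.228 and 0.124 with an estimated correlation). Among blood cell markers at 3 h, the neutrophil and T cell lists passed. Neutrophil markers rose in 11 of 16 cases, with Clec4e (4.01), Trem1 (3.19) and S100a8 (1.59), but Csf3r (0.41), Cxcr2 (0.34) and Ly6g (0.29) were not called (adjusted p = 6.8e-14, but adjusted p = 0.108 with an estimated correlation). Of 20 T cell markers, only Cd5 fell by at least 2-fold (-1.07), and 13 were lower by adjusted p with any fold (list adjusted p = 0.00958, but adjusted p = 0.54 with an estimated correlation).

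The largest falls at 3 h were Arhgdig (-4.04), the potassium channel gene Kcnj16 (-3.61), the adrenergic receptor gene Adra1d (-3.23), Fgfr4 (-3.21), Pitpnm3 (-3.14), Fam171a2 (-2.92), Greb1 (-2.75), Dzip1l (-2.64), Rims3 (-2.64) and Slc40a1 (-2.61), the iron exporter ferroportin. Slc40a1 (chromosome 1, 45908068 to 45926523) was at 469 ± 6.94 CPM in PBS and 77.0 ± 57.9 at 3 h. In 3 h replicate 3 it was at 144 CPM and in the other 2 libraries at 43.0 and 44.0. Without 3 h replicate 3 the falls were larger, at -5.78 for Kcnj16, -4.06 for Adra1d, -4.51 for Fgfr4, -3.90 for Pitpnm3, -3.40 for Greb1, -3.37 for Rims3 and -3.42 for Slc40a1. Arhgdig, Adra1d and Fam171a2 overlap other genes, so their counts are uncertain.

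In all, 977 genes were higher and 808 lower at 3 h than in PBS (edgeR quasi-likelihood, Benjamini-Hochberg), and 6896 passed the adjusted p alone. All 3 libraries of 1 group lay beyond the other 3 for 52.5% of genes, where chance gives 10% for 3 against 3. Among KEGG terms in the deposited annotation, cytokine-cytokine receptor interaction held 67 higher genes of 203 (14.3 expected, adjusted p = 7.32e-27) and TNF signalling 43 of 106 (7.5 expected). Of the 977 higher genes, 647 overlap no other gene.

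At 6 h, 20 of 25 chemokines rose, and 7 of 14 splenic macrophage markers were called lower than in PBS. Cxcl1 was at 344 ± 50.1 CPM (SD, n = 3), 8.82 ± 0.24 (SE) above PBS on the log2 scale (adjusted p = 4.01e-11). Csf3 (chromosome 11, 98701263 to 98703629) rose by 8.40, Irg1 (chromosome 14, 103046977 to 103056573) by 7.92, Cxcl2 by 7.78, Adamts4 by 7.59, Ccl2, a monocyte-attracting chemokine, and Il6 each by 7.46, Ptgs2 by 7.44 and Cxcl11 by 6.75. Without PBS replicate 1 the rise of Irg1 was 8.52. Il22 had 0 counts in PBS and 798 at 6 h, at least 65.6-fold higher. Its sequence shares 40.4% of its words with another gene, and Cxcl11 overlaps Art3, so both counts are uncertain.

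Among the largest falls at 6 h, Cd163, the haptoglobin-haemoglobin scavenger receptor (chromosome 6, 124304656 to 124330527), was at 46.5 ± 1.16 CPM in PBS and 0.756 ± 0.195 at 6 h (-5.77 ± 0.40, adjusted p = 1.27e-07). Kcnj16 (-6.31), the eosinophil-associated chemokine receptor Ccr3 (-6.25), the vasoactive peptide gene Edn3 (-5.42), Fgfr4 (-5.29), Pitpnm3 (-4.69), Gdf10 (-4.68), Kazald1 (-4.66), Cx3cr1, the fractalkine receptor (-4.50), and Arhgdig (-4.43) also fell. Cx3cr1 and Itgad, a macrophage integrin gene, overlap other genes, so their counts are uncertain. Of 14 splenic macrophage markers, 7 fell at 6 h, among them Slc40a1 (-3.83), Cd5l (-2.06), Itgad (-1.67) and Timd4 (-1.38), and 2 rose, the scavenger receptor Marco (2.81) and Adgre1, which encodes F4/80 (1.11, but 0.94, under the fold limit, with quantile normalization). Siglec1 was not called (-0.16). The list median was -1.06 (adjusted p = 0.00672, but adjusted p = 0.258 with an estimated correlation).

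The inflammation lists at 6 h had 17 of 19 cytokines, 20 of 25 chemokines and 22 of 23 brakes higher and 0, 2 and 1 lower, with medians of 4.24, 4.33 and 2.32. Adjusted p was 4.26e-29, 9.58e-44 and 2.12e-37, and 0.0254, 0.0108 and 0.0299 with an estimated correlation. Type I interferon genes rose in 23 of 24 cases and interferon-gamma genes in 17 of 20 (adjusted p = 9.47e-58 and 9.97e-56, and 0.0254 and 0.0108 with an estimated correlation). Ifng itself, the T and natural killer cell interferon, was at 44.0 ± 21.0 CPM against 0.492 in PBS (6.24). Genes of class I antigen presentation, which show peptides to CD8 T cells, rose in 12 of 17 cases at 6 h and 4 of 17 at 3 h. Examples at 6 h were Nlrc5, the class I transactivator (2.15), Psmb9 (1.30) and B2m (1.08, but 0.73, under the fold limit, with quantile normalization). Psmb9 and B2m overlap Tap1 and Patl2, so their counts are uncertain. The list had adjusted p = 3.78e-11 at 3 h and 1.84e-16 at 6 h, but adjusted p = 0.146 and 0.0791 with an estimated correlation.

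Other lists at 6 h moved in part. Coagulation genes rose in 7 of 20 cases, with F10, a clotting protease gene, at 2.35, and Thbd, which encodes the anticoagulant thrombomodulin, fell by 2.02 (adjusted p = 0.00347, but adjusted p = 0.456 with an estimated correlation). Apoptosis genes rose in 7 of 22, such as the death ligand gene Tnfsf10 (2.35) and the death receptor gene Fas (2.18), together with the inhibitor Cflar (1.93), with adjusted p = 6.55e-05 but adjusted p = 0.0896 with an estimated correlation. Stromal genes fell in 3 of 14 cases, namely Tcf21 (-3.26), a mesenchymal transcription factor, Col1a1 (-1.59) and Col1a2 (-1.31), which overlaps another gene, with adjusted p = 0.00701 but adjusted p = 0.297 with an estimated correlation. Toll-like receptor and NF-kB genes rose in 7 of 29 cases and fell in 2 (adjusted p = 0.15 with an estimated correlation), inflammasome genes rose in 7 of 16 and 1 fell (0.041), acute phase genes rose in 14 of 21 (0.0547), immediate early genes in 10 of 14 (0.0773), metallothionein genes in 7 of 15 with 2 falling (0.041), glucocorticoid-induced genes in 6 of 14 with Cd163 falling (0.0636), heat shock genes in 2 of 14 (0.168) and neutrophil markers in 12 of 16 (0.15), each p being an adjusted p with an estimated correlation. All of these passed with the preset correlation.

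In all, 1162 genes were higher and 1349 lower at 6 h than in PBS, and 8602 passed the adjusted p alone. With quantile normalization more were higher (1273) than lower (1118). Groups lay fully apart for 61.4% of genes (10% by chance). Cytokine-cytokine receptor interaction was again the leading KEGG term among higher genes (69 of 203, 16.8 expected, adjusted p = 3.24e-24). Of the 1162 higher genes, 764 overlap no other gene.

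At 12 h the acute phase gene Saa3 led, and more genes of the glycolysis and hypoxia-inducible factor, complement and class I presentation lists were called higher than at 3 or 6 h. Saa3 (chromosome 7, 46711998 to 46715676) was at 782 ± 15.6 CPM against 3.30 ± 1.78 in PBS (SD, n = 3), a rise of 7.83 ± 0.32 (SE) on the log2 scale (adjusted p = 1.01e-09). Irg1 rose by 7.70 (8.30 without PBS replicate 1), Csf3 by 7.47, Cxcl11 by 7.27, Ptgs2 by 6.78, Lox, which cross-links collagen, by 6.48, Cxcl1 by 6.44, Cxcl2 by 6.32 and Ccl7 by 6.28. Psg22, a pregnancy-specific glycoprotein gene (chromosome 7, 18718090 to 18727248), had 0 counts in PBS and 606 at 12 h, at least 49.4-fold higher.

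Glycolysis genes and targets of the hypoxia-inducible factor rose in 18 of 22 cases at 12 h, against 4 at 3 h and 5 at 6 h. They included the lactate exporter gene Slc16a3 (2.75), Adm (2.76), Pkm (1.46) and Ldha (1.21, but 0.93, under the fold limit, with quantile normalization), with a median of 1.40 and adjusted p = 4.54e-15, but adjusted p = 0.0945 with an estimated correlation. At 3 and 6 h the list had adjusted p of 0.00299 and 7.15e-05, but adjusted p = 0.525 and 0.372 with an estimated correlation. Gapdh, Pgk1, Pgam1, Eno1 and Pkm share 31.1% to 63.8% of their words with another gene, so their levels are uncertain, as is that of Adm, which overlaps another gene. Complement genes rose in 10 of 22 cases, with Cfb at 4.18, C3 at 1.78 and the inhibitor Serping1 at 1.69, while C6 (-2.73) and the complement receptor gene Cr2 (-1.36) fell. The adjusted p was 4.18e-05, but adjusted p = 0.168 with an estimated correlation, and at 3 and 6 h the list did not pass (0.5 and 0.134). Cfb shares 80.8% of its words with an overlapping gene model. Class I presentation rose in 15 of 17 cases (adjusted p = 6.17e-23, 0.041 with an estimated correlation), with H2-K1 at 2.16 (2.97 without PBS replicate 3).

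Few cell cycle and red cell genes passed 2-fold at 12 h, although most passed the adjusted p. None of 23 cell cycle genes was called at 3 or 6 h, and at 12 h all 23 were lower by adjusted p, with 2 past 2-fold, the cyclin gene Ccne2 (-1.62), which overlaps Ints8, and the ribonucleotide reductase subunit Rrm2 (-1.32). Mki67, a marker of dividing cells, was at 1869 CPM in PBS and 993 at 12 h (-0.91, but -1.15 and called with quantile normalization). The list median was -0.81 (adjusted p = 5.57e-11, but adjusted p = 0.258 with an estimated correlation). The list also passed at 6 h (median -0.27, adjusted p = 0.035, but adjusted p = 0.697 with an estimated correlation). Of 19 erythroid genes, 18 were lower by adjusted p at 12 h and 3 past 2-fold, the blood group gene Rhd (-1.38), the erythroid transcription factor Klf1 (-1.26) and the spectrin gene Sptb (-1.14), with adjusted p = 3.44e-07 but adjusted p = 0.415 with an estimated correlation. Haemoglobin genes took 2.07% to 2.76% of counts in the PBS libraries, 2.67% to 2.96% at 3 h, 1.81% to 2.13% at 6 h and 1.17% to 1.41% at 12 h.

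Of 18 B cell markers, 2 fell at 12 h, Fcer2a, the low-affinity IgE receptor CD23 (-2.71), and Cr2, and 12 were lower by adjusted p with any fold (adjusted p = 0.000412, but adjusted p = 0.317 with an estimated correlation). Fcer2a also fell by 1.93 at 6 h, when the list had adjusted p = 0.0122 but adjusted p = 0.498 with an estimated correlation. Splenic macrophage markers fell in 7 of 14 cases at 12 h and rose in 2, with Slc40a1 at -3.92 (adjusted p = 0.00678, but adjusted p = 0.258 with an estimated correlation).

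The largest falls at 12 h were Ccr3 (-6.14), Cd163 (-5.69), Kcnj16 (-5.13), Edn3 (-5.11), the lectin gene Cd207 (-5.10), Clps (-4.78), the mannose receptor gene Mrc1 (-4.71), Abca9 (-4.49), Cx3cr1 (-4.24) and Cd209a (-4.22). Mrc1 (chromosome 2, 14229392 to 14332057) was at 194 ± 5.93 CPM in PBS and 7.31 ± 0.285 at 12 h. Clps encodes pancreatic colipase and was at 41.0, 76.1 and 50.1 CPM in the PBS libraries and 0.75, 4.62 and 0.155 at 12 h. Without 12 h replicate 2 its fall was -6.56. The pancreas markers fell in 13 of 16 cases at 12 h (median -3.35, adjusted p = 0.0145, but adjusted p = 0.696 with an estimated correlation, and 16 of 16 when adjusted over the list alone), and none was called at 3 or 6 h (medians -1.32 and -1.57). Their amount varied between libraries of one group, from 26.7 to 1838 summed CPM at 6 h.

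In all, 1146 genes were higher and 1217 lower at 12 h than in PBS, and 8597 passed the adjusted p alone, with groups fully apart for 61.8% (10% by chance). With quantile normalization more were higher (1234) than lower (1102). The inflammation lists had 16 of 19 cytokines, 18 of 25 chemokines (2 were lower) and 17 of 23 brakes higher, and 22 of 24 type I and 18 of 20 interferon-gamma genes. Their adjusted p with an estimated correlation was 0.041, 0.0172, 0.0361, 0.0337 and 0.0108. With the same kind of p, acute phase genes rose in 16 of 21 cases and 1 fell (0.046), inflammasome genes rose in 7 of 16 (0.041), metallothionein genes in 6 of 15 with 1 falling (0.0425), glucocorticoid-induced genes in 6 of 14 with Cd163 falling (0.0425), immediate early genes in 8 of 14 with 1 falling (0.157), neutrophil markers in 12 of 16 (0.196), apoptosis genes in 6 of 22 (0.102), coagulation genes in 8 of 20 with 1 falling (0.372), heat shock genes in 3 of 14 (0.297) and Toll-like receptor and NF-kB genes in 6 of 29 with 2 falling (0.278). All of these passed with the preset correlation. Among KEGG terms of lower genes at 12 h, protein digestion and absorption (25 of 69, 5.3 expected, adjusted p = 2.87e-09) and pancreatic secretion (25 of 79, 6.0 expected, adjusted p = 4.2e-08) led. Of the 1217 lower genes, 27 followed the mean of the pancreas markers in their deviations from group means (r above 0.9, across 12 libraries). The 13 pancreas markers called lower entered both that mean and the genes searched, so this count is not separate from them.

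**Figure D3:**
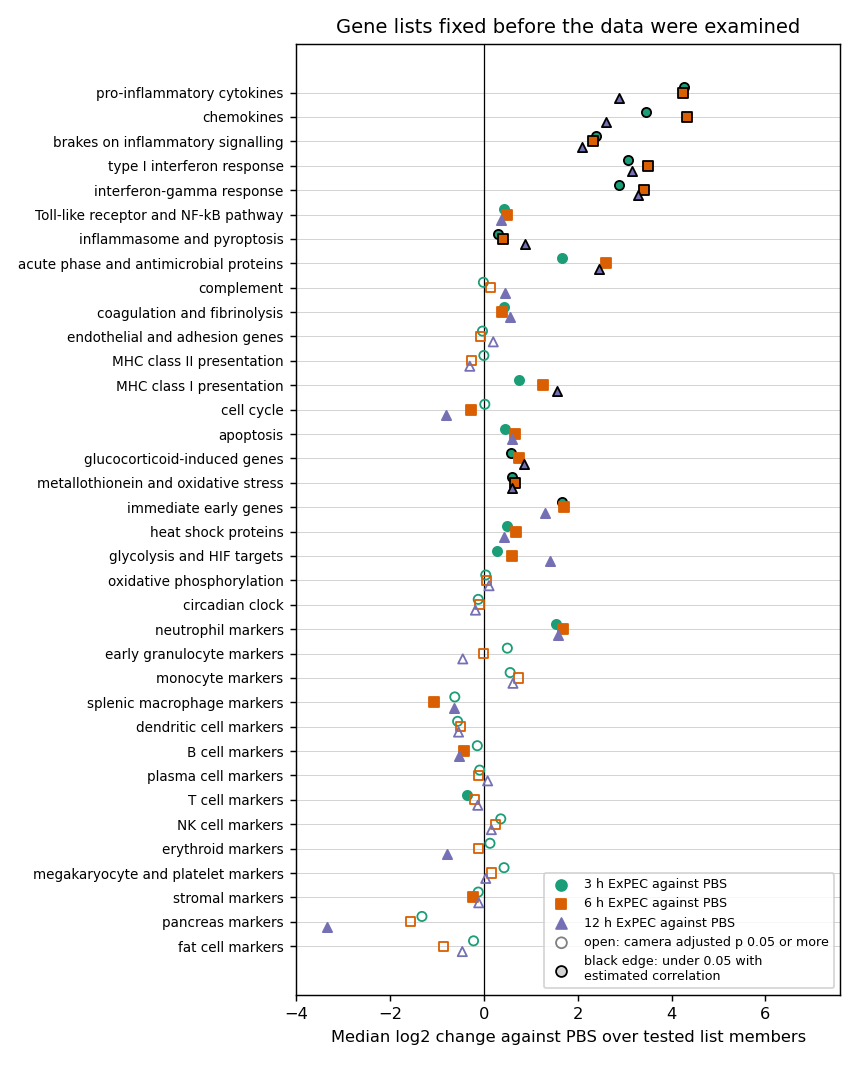
Median log2 change against PBS of the tested members of each of the 36 gene lists at 3 h (circles), 6 h (squares) and 12 h (triangles). Filled symbols passed camera at an adjusted p under 0.05, and black edges mark those that also passed with an estimated correlation.

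**Figure D4:**
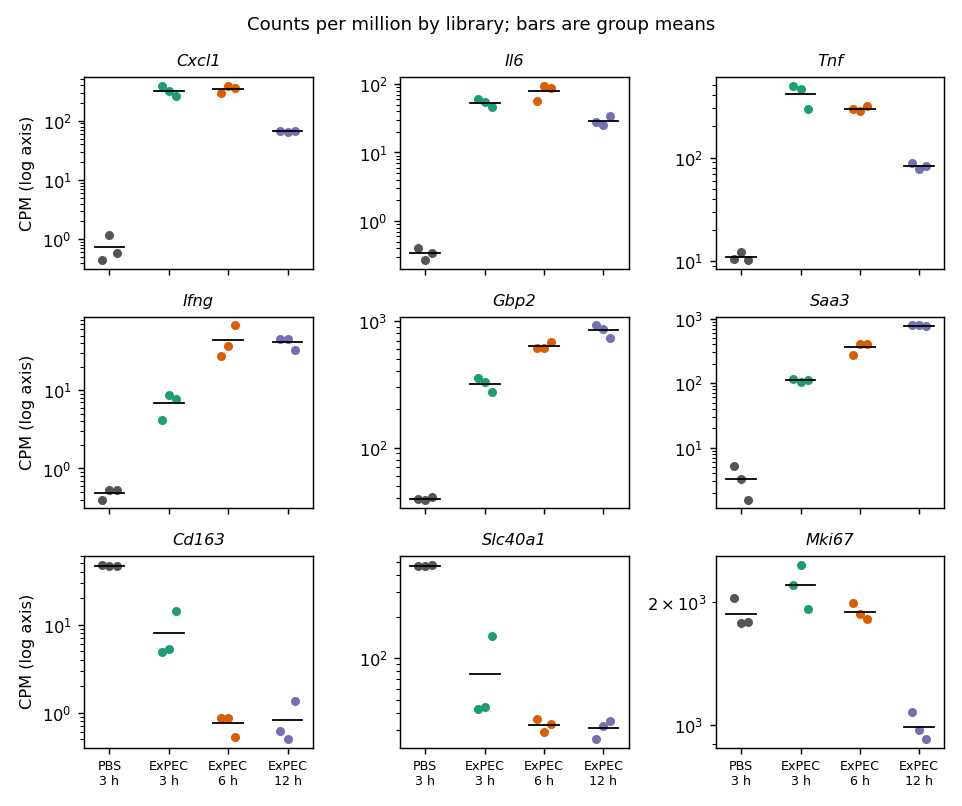
CPM on a log axis for 9 genes in each of the 12 libraries (points) with the group means (bars). Cxcl1, Il6 and Tnf were lower at 12 h than at 6 h, the mean of Saa3 was highest at 12 h, and for Cd163 and Slc40a1 the libraries at 6 and 12 h lie below those of PBS.

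Across the 3 times, 700 genes were higher and 434 lower at every time. Called at 3 h alone were 93 higher and 100 lower genes, at 6 h alone 79 and 287, and at 12 h alone 210 and 395, although a call at one time and not another was not itself tested here. All 3 comparisons used the same PBS libraries, so their chance values are shared. Independent lists would share 5.03 higher and 5.13 lower genes. In 20 simulations of unchanged groups against these controls the number was 0. Without true changes almost no gene can be called, so this 0 does not measure what shared controls add to the overlaps. Log2 changes correlated across genes with r = 0.896 between 3 and 6 h, 0.758 between 3 and 12 h and 0.886 between 6 and 12 h (simulated means 0.5, 0.495 and 0.524). The covariances were 0.678, 0.543 and 0.756, against simulated values of 0.0278, 0.0275 and 0.028. The difference, an estimate of the shared effect, was a covariance of 0.65, 0.515 and 0.728. For the overlaps of calls, 3 control libraries could not be split, and part of the excess may come from the shared controls.

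The comparison of 6 h with 3 h of infection asked which genes moved between these times, without the PBS libraries in the contrast. The interferon-gamma gene rose, and 2 of 20 genes of its response list passed 2-fold. Ifng went from 6.90 ± 2.38 to 44.0 ± 21.0 CPM (2.68 ± 0.33 on the log2 scale, adjusted p = 0.000216). By adjusted p with any fold, 16 of the 20 response genes were higher, and the 2 past 2-fold were Iigp1 and Gbp4 (1.08 each; Iigp1 0.98, under the fold limit, without 3 h replicate 3, and Gbp4 0.98 with quantile normalization), with a list median of 0.55 (adjusted p = 2.32e-19, 0.0425 with an estimated correlation). Gbp4 overlaps Gbp8 and Gbp9. The largest rises were Tubb3, a neuronal tubulin gene (2.77), Ifng, the stress pseudokinase gene Trib3 (2.53), the ubiquitin-like gene Ubd (2.43) and Lox (2.29). Chemokines that rose included Cx3cl1 (1.63), Cxcl9 (1.34) and Ccl22 (1.24), 5 of 25 in all, while Ccl24 fell by 1.59 (adjusted p = 0.000413, but adjusted p = 0.258 with an estimated correlation and 0.161 with quantile normalization).

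The largest falls from 3 to 6 h were Zbed6 (-5.11), Ccr3 (-3.69), Cd163 (-3.23), Kazald1 (-2.83) and Mrc1 (-2.80). Zbed6 lies within Zc3h11a, shares 100% of its words with another gene, and was at 1.77, 50.8 and 60.0 CPM in the 3 libraries at 3 h, so this fall is uncertain. Without 3 h replicate 3 the fall of Ccr3 was -1.62 and that of Cd163 -2.60, and Ccr3 missed the adjusted p without 6 h replicate 2 (-3.57, adjusted p = 0.0607) and with only the 2 groups in the fit (-3.71, adjusted p = 0.0541). In all, 114 genes were higher and 275 lower, which is 29.3% higher. With quantile normalization 156 were higher and 214 lower, or 42.2% higher. Without 3 h replicate 3 they were 121 and 228, or 34.7% higher. Groups lay fully apart for 31.9% of genes (10% by chance).

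Of 36 lists, 17 passed from 3 to 6 h, with few members past 2-fold. Acute phase genes rose in 4 of 21 cases, with Saa3 at 1.70 and Lcn2 at 1.27 (adjusted p = 9.24e-08, but adjusted p = 0.196 with an estimated correlation), and class I presentation genes were higher by adjusted p in 14 of 17 cases with none past 2-fold (adjusted p = 6.31e-13, but adjusted p = 0.104 with an estimated correlation). Splenic macrophage markers fell in 2 of 14 cases and Marco rose (1.02, but 1.00 and 0.99, under the limit, without 6 h replicate 2 or 3, and 0.97 with quantile normalization), with adjusted p = 0.00234 but adjusted p = 0.198 with an estimated correlation. Stromal genes were lower by adjusted p in 8 of 14 (adjusted p = 8.59e-06, but adjusted p = 0.0945 with an estimated correlation). The other 11 that passed were the brake, type I interferon, inflammasome, complement, apoptosis and glycolysis lists upwards and the coagulation, cell cycle, B cell, erythroid and megakaryocyte lists downwards. None of these 11 held with an estimated correlation, where adjusted p was 0.18 to 0.697. Of them, the type I interferon, complement, coagulation and apoptosis lists also missed with quantile normalization. Fry, which tests a list against no change and not against other genes, did not pass for the type I interferon, coagulation and megakaryocyte lists (0.0645 to 0.238).

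Between 6 and 12 h of infection, transcripts of several cytokines and chemokines and of an endothelial adhesion receptor fell. Sele, which encodes the adhesion molecule E-selectin (chromosome 1, 164048234 to 164057677), went from 25.6 ± 5.61 to 1.77 ± 0.537 CPM (-3.76 ± 0.25 on the log2 scale, adjusted p = 2.67e-06). Mmp13 (-3.54), Fgf23 (-2.75), Cxcl1 (-2.37) and Ccl17 (-2.31) were the other leading falls. Of 19 cytokines 8 fell, including Tnf (-1.82), Il12b (-1.80) and Il6 (-1.46), while Ifng was not called, with adjusted p = 9.47e-16 but adjusted p = 0.0517 with an estimated correlation. Of 25 chemokines 12 fell (13 when adjusted over the list alone) and Cxcl9 rose by 1.03, but by 0.94, 0.99 and 0.95, under the limit, without 6 h replicate 1, 6 h replicate 2 or 12 h replicate 1 (list adjusted p = 5.41e-20, 0.0258 with an estimated correlation).

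Among the largest rises from 6 to 12 h were Psg22 (2.98), Ndufa4l2, a mitochondrial gene that hypoxia induces (2.92), Lrrn1 (2.50) and the Wnt antagonist gene Dkk3 (2.48). Ndufa4l2 overlaps Shmt2. Glycolysis genes and targets of the hypoxia-inducible factor rose in 4 of 22 cases, among them the factor's targets Bnip3 (1.86), Egln3 (1.37, but 0.86 without 12 h replicate 1) and the glycolysis gene Tpi1 (1.30), with adjusted p = 5.87e-14 but adjusted p = 0.0986 with an estimated correlation. Bnip3 shares 27.8% of its words with another gene and Tpi1 overlaps Spsb2, so their counts are uncertain. All 19 erythroid genes and 22 of 23 cell cycle genes were lower by adjusted p, with 0 and 1 past 2-fold (adjusted p = 8.2e-17 and 1.02e-17, but adjusted p = 0.168 and 0.136 with an estimated correlation). Complement genes were higher by adjusted p in 14 of 22 cases (adjusted p = 2.63e-07, but adjusted p = 0.0916 with an estimated correlation). The other 8 of 14 lists that passed were class I presentation and stromal genes upwards and the brake, type I interferon, Toll-like receptor, immediate early, early granulocyte and pancreas lists downwards. None of these 8 held with an estimated correlation, where adjusted p was 0.268 to 0.697, and fry did not pass for the pancreas list (0.252). In all, 321 genes were higher and 189 lower (256 and 212 with quantile normalization), and groups lay fully apart for 43.2% of genes (10% by chance). Cytokine-cytokine receptor interaction was the leading KEGG term among lower genes (23 of 203, 2.7 expected, adjusted p = 1.18e-13).

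Of the 180 list tests, 93 passed and 28 held with an estimated correlation. Those 28 were the cytokine, chemokine, brake, both interferon, inflammasome and metallothionein lists against PBS at all 3 times, glucocorticoid-induced genes at 3 and 12 h, immediate early genes at 3 h, acute phase and class I presentation genes at 12 h, the interferon-gamma list between 3 and 6 h, and chemokines between 6 and 12 h. Some of these lists share members, so their passes are not independent. Il1a, Il1b and Il18 are in both the cytokine and inflammasome lists, and Mt2 is in the metallothionein and glucocorticoid lists. Dusp1 is in the brake and glucocorticoid lists, and Socs1 in the brake and interferon-gamma lists. List counts adjusted over the list alone equalled those over all genes except where stated, and for acute phase genes, where 16 rose at 3 h and 15 at 6 h. In 27 of the 180 tests, none of which passed, the list median, mean and test differed in sign.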

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

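The tests of pooled sexes and carry-over and the tests of the pancreas genes were chosen only after the results were seen.

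In all, 6 genes were called higher than PBS at one time of infection and lower at another, which marked them as a difference between groups. Picking genes with opposite calls fixes a large difference between the times, so a test of that difference adds no evidence of its own. The fitted log2 change from 3 to 12 h was 3.18 for the ion channel gene Asic2 (SE 0.40), 2.63 for Lpin3, a phosphatidate phosphatase gene (SE 0.15), and 2.26 for 4930455G09Rik (SE 0.35). At 3 h Asic2 was at 0.191 ± 0.158 CPM and 4930455G09Rik at 0.128 ± 0.0445 (SD). Both are near the level of 3 counts in 1 library (0.12 to 0.30 CPM), so the size of these 2 changes is uncertain. For Ido2, an enzyme of tryptophan breakdown, it was 3.37, but with 3 counts at 3 h, below the floor, and 111 at 12 h the ratio was 24.9 (95% counting interval 8.31 to 123). Lpin3, which overlaps Gm16751, was at 9.66 CPM in PBS and 4.70, 8.61 and 29.9 CPM at 3, 6 and 12 h, and overlaps Gm16751. AI118078 had 1 count at 12 h, below the floor, and its ratio to 3 h was 0.0354 (0.000853 to 0.223) and to 6 h 0.0255 (0.00063 to 0.151). Its fitted changes were -2.15 and -2.54. The latter depends on the settings, running from -5.19 to -2.42, and the former was not run under other settings. Ndufa4l2 changed by 2.92 from 6 to 12 h (SE 0.20) and overlaps Shmt2. PBS was sampled at 3 h alone, and no explanation of these differences was tested.

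Transcripts of both sexes were high in every library. Xist, made from the inactive X chromosome of females, was at 767 to 1038 CPM together with the Y-linked genes Ddx3y, Kdm5d, Eif2s3y and Uty above the floor in 12 of 12 libraries. Carry-over between libraries of single-sex mice would vary, but the highest library held 1.34 times the Y-linked sum of the lowest and 1.35 times the Xist. Sequence shared with X-linked homologues accounted for at most 0.81% of the Y-linked CPM. What stays open is that each library may hold RNA of male and female mice, and no biological explanation was tested. If so, the SD, SE and coefficient of variation given here describe the spread between pools, not between single mice.

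In 67 cases, in 50 genes, 1 library of a group was at least 8-fold below the other 2, which were at 5 CPM or more. The low value was not always near 0, as for mt-Nd1 at 157 CPM in 3 h replicate 1. Overlap with another gene was no more frequent among the 50 genes (26%) than among others (35.15%, odds ratio 0.65, Fisher exact p = 0.234), and 7.5% of the cases lay in the 3 libraries with the fewest counts. Of the 21 genes that did not follow the pancreas genes, a subset taken after that test, 8 overlapped another gene (Fisher exact p = 0.82). The explanation first written for overlap named near-identical genes too, while its test measured overlap alone. Of the 50 genes, 29 followed the pancreas genes (r above 0.9 of deviations from group means), some of them members of the pancreas list such as Clps. In a test devised after the overlap test, 65% of the 20 others with transcripts had at least 20% of their words in another gene. Among 999 genes the share was 9.71% (odds ratio 17.3, Fisher exact p = 5.61e-09). Reads shared between near-identical sequences may account for these 13 of 20. The other 7 shared at most 1.2% of their words, so this does not cover them.

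Pancreas genes varied between libraries of one group and were lowest at 12 h. The mean log2 CPM of 16 pancreas genes was 6.46, 7.28 and 6.72 in PBS, 5.22, 4.54 and 6.34 at 3 h, 0.42, 5.40 and 6.27 at 6 h, and 2.34, 4.62 and -0.28 at 12 h. Their deviations from group means correlated with a median r of 0.99 (across 12 libraries), so differing amounts of pancreas tissue taken with the spleen may explain the variation between libraries. The 12 h and PBS groups differed by -4.597 in the mean (exact permutation p of 0.1, the smallest that 3 against 3 libraries allow, which decides nothing). An effect of infection and uneven dissection cannot be told apart there, since no value used here measures pancreas tissue apart from these genes.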

How the results depend on the processing

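Leaving out PBS replicate 2 and 3 h replicate 3 together, leaving out overlapping genes, and the list and KEGG counts with 1 library left out were chosen only after the results were seen. The counts of genes stayed within 1.5 times under the smaller prior count, no filter, DESeq2 size factors, quantile normalization, DESeq2 and the fit of only the 2 groups compared. With 1 library left out in turn, counts higher and lower were 900 to 1040 and 720 to 987 at 3 h, 1148 to 1202 and 1326 to 1420 at 6 h, 1125 to 1179 and 1146 to 1287 at 12 h, 91 to 128 and 211 to 277 from 3 to 6 h, and 302 to 349 and 184 to 225 from 6 to 12 h. The F-test then passed for 9652 to 10494 genes, 90 to 98 lists and 240 to 274 KEGG terms passed. Without a minimum fold the counts rose by construction, to 3637 and 3259, 4401 and 4201, 4493 and 4104, 1090 and 1263, and 2111 and 2112. KEGG terms went from 267 to 306, and their number moved by over 1.5 times in 5 of 10 cases. List tests passing fell from 93 to 28 with the estimated correlation, which widens the test by construction, and were 122 with fry, which tests against no change and not against other genes, 99 with quantile normalization and 95 with the replicate block. Without overlapping genes fewer genes were counted, 647 higher at 3 h, 764 higher at 6 h and 6833 by the F-test. Without the 2 libraries the counts were 1015 and 936, 1180 and 1332, 1175 and 1185, 122 and 207, and 343 and 187. With the replicate block they were 970 and 805, 1168 and 1345, 1143 and 1211, 106 and 241, and 315 and 189. The numbers did not pair the libraries, since r of deviations was -0.271 to 0.158 for 18 pairs with the same number and -0.341 to 0.358 for 36 others. List tests lost or gained a pass in 65 and 0 cases with the estimated correlation, 4 and 33 with fry, 5 and 11 with quantile normalization and 0 and 2 with the replicate block, and none turned. Of 235 results of genes named or picked by the rule, 219 kept their call under every setting run on single genes. These were 18 or 19 for each, without the settings of no minimum fold, the 2 libraries out together and overlapping genes left out. Over the settings run on the others, the call was lost 28 times (17 by fold alone) and gained 5 times, and none turned. The cause was not tested. DESeq2 gave no adjusted p for 3 of them, and the prior count does not enter the list tests. Depth limits genes near 0.12 to 0.30 CPM, where 3 counts or fewer were seen.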

Other observations

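Some fixed lists that did not pass as a whole against PBS held called genes. In the circadian clock list, Dbp, a clock output gene, fell at 3, 6 and 12 h (-2.07, -2.59 and -2.65), Nr1d1 fell at 6 and 12 h (-2.27 and -3.96) and Nfil3 rose (2.12, 2.62 and 3.00). Of 18 clock genes 2 rose and 4 fell at 3 h, 3 and 6 at 6 h, and 2 and 7 at 12 h (list adjusted p = 0.367, 0.314 and 0.187). Dbp and Nr1d1 overlap Sphk2 and Thra. For clock genes only the 3 h values are matched in time with PBS. At 6 and 12 h the time of sampling and the infection change together, so those changes cannot be credited to infection alone. Endothelial genes rose in 3, 5 and 7 of 17 cases and fell in 3, 2 and 2 (0.284, 0.309 and 0.13), with Sele at 6.00, 5.42 and 1.65 and the angiopoietin receptor gene Tek at -1.94, -2.93 and -2.28. Of 15 class II presentation genes 3, 2 and 2 rose and none fell past 2-fold (0.369, 0.972 and 0.557), among them Cd40, a costimulatory receptor gene (1.39, 1.96 and 1.20). None of 25 oxidative phosphorylation genes was called by edgeR (0.934, 0.759 and 0.301), although 5, 8 and 10 passed the adjusted p with a smaller change.

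Cell marker lists that did not pass against PBS also held called genes. Monocyte markers rose in 3, 5 and 5 of 13 cases and fell in 3, 4 and 4 (adjusted p = 0.201, 0.573 and 0.354), with Vcan, which overlaps another gene, at 3.08, 3.64 and 3.71. Dendritic cell markers rose in 1, 4 and 4 of 14 and fell in 1, 4 and 4 (0.428, 0.692 and 0.433), with Fscn1, an actin bundling gene of mature cells, at 2.12, 3.20 and 3.24 and the chemokine receptor gene Xcr1 at -1.40, -2.30 and -2.38. Natural killer cell markers rose in 1, 2 and 4 of 12 and fell in 1, 1 and 1 (0.361, 0.314 and 0.187), with granzyme B (Gzmb) at 3.42, 3.78 and 3.56. Early granulocyte markers rose in 1, 1 and 1 of 11 and fell in 0, 0 and 3 (0.0654, 0.404 and 0.63), plasma cell markers rose in 1, 1 and 1 of 10 and fell in 0, 1 and 1 (0.865, 0.884 and 0.798), and fat cell markers fell in 0, 3 and 3 of 10 (0.314, 0.157 and 0.31). None of 13 megakaryocyte markers was called by edgeR, while 9, 3 and 4 passed the adjusted p with a smaller change (0.108, 0.663 and 0.884).

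Other splits of the libraries were run for each comparison. The real split called 1785, 2511, 2363, 389 and 510 genes in the 5 comparisons, and the highest other split 1, 1, 0, 1 and 3. Every other split mixed libraries of both real groups, so real differences widened the spread within its groups. The low counts of the other splits thus do not show how many genes groups without a difference would give. In each, 1 of the 10 splits gave as many genes, and 10 splits are too few for a share under 0.05. For the 4 groups together, 1 of 100 splits, the real one, gave as many as 10359 genes, and the highest other gave 4867. Real differences lay within groups of those other splits too. A share of 1 in 100 makes a chance split unlikely there, but 100 splits cannot exclude it.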
